A study of Caenorhabditis elegans with 12 samples.

How the data were processed

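The 12 libraries came from wild-type (N2) and hlh-30(tm1978) animals of both sexes, 3 per group, from 3 independent extractions per the labels, so that p-values measure the spread between these samples. Per the labels' protocols, animals were kept on OP50 at 20 °C, males came from heat shock of L4 larvae and were maintained by crossing, and prefertile to day 1 adults were picked by hand and sequenced paired-end. Groups were taken from the labels alone.

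Reads were aligned with STAR 2.7.0e to WBcel235 (ce11) and counted with RSEM 1.3.1, per the submitters' processing notes. The deposited RSEM expected counts per gene were used, rounded to whole numbers, and TPM computed from them in alternatives only. The strand setting of the counting, the authors' annotation release, trimming and read filters are not given in the sources used here, so that genes that overlap or have near-identical copies carry uncertain values. Of 46904 genes in the files 46817 matched annotation release 115, which gave names, positions and biotypes, and the other 87 held at most 0.013% of a library's counts. The names spe-7, atg-101 and opt-2 of the lists had no match, and 7 mitochondrial genes were named by their start position.

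Total counts were 30269857, 27232936 and 29420555 in wild-type hermaphrodites, 27688012, 26135726 and 29518949 in wild-type males, 29082558, 23815305 and 26146155 in hlh-30 hermaphrodites and 27858891, 25062528 and 28378922 in hlh-30 males. At these depths the floor of 3 counts corresponds to 0.104 to 0.12 CPM. Ribosomal RNA genes held 5.32 to 14.2% of the counts of hermaphrodites and 6.58 to 22.7% of those of males, the highest in hlh-30 male library 3. Spread between replicates exceeded counting error, with chi-square per degree of freedom from 22.6 to 518. Intervals from floors cover counting error alone.

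Genes with enough counts by filterByExpr, 16645 in all, were scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3), by its quasi-likelihood F test with robust estimates and Benjamini-Hochberg adjustment over the genes of a comparison. All 12 libraries entered 1 model of 4 group means with 8 residual degrees of freedom. The 5 comparisons were sex in the wild type, sex in hlh-30, genotype in hermaphrodites, genotype in males and the interaction, the last being the genotype effect in males minus that in hermaphrodites. Genes were called at an adjusted p under 0.05. Standard errors are the log2 fold change over the square root of F.

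The 31 gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. They cover reproduction (vitellogenins, oocyte and eggshell, early embryo, germline, major sperm proteins, spermatogenesis, male tail and male neurons, sex determination), autophagy and lysosome (autophagy, lysosome, lysosomal lipases, V-ATPase, reported HLH-30 targets) and immunity (C-type lectins, lysozymes, antimicrobial peptides and caenopores, PMK-1 pathogen response, intracellular pathogen response). The others are DAF-16 targets, heat shock, detoxification, lipid metabolism, collagens, neuropeptides, ribosomal proteins, proteasome, mitochondrial genome, neurons, body wall muscle, pharynx and intestine. Overlaps were tested with Fisher's exact test, and X-linked against autosomal genes with camera.

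Named genes followed a rule set before the data were examined. It takes hlh-30 first, then per comparison the 5 largest rises and 5 largest falls among called genes with a mean count of at least 10 per library in both groups (all 4 for the interaction) and no overlap between the groups (not asked of the interaction). From each list it takes the 2 members with the smallest p and every called member of the autophagy, lipase, vitellogenin, lysozyme and HLH-30 target lists. Of genes at 0 in a group it takes the number and the 2 with the highest mean count, with a lower bound from 3 counts per library. Of male-biased genes lower in hlh-30 males it takes the 5 largest falls. Examples printed are drawn from these, and others are marked as chosen after their values were seen.

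Replicate numbers were checked as pairs by the correlation of residuals over 13006 genes with a mean count of at least 50. Wild-type and hlh-30 males correlated at 0.82, 0.76 and 0.88 for equal numbers (highest other 0.65) and hlh-30 hermaphrodites and hlh-30 males at 0.20, 0.50 and 0.57 (highest other 0.40), so that results with the replicate number as a block are given beside these 2 comparisons where they change a call. Wild-type and hlh-30 hermaphrodites gave −0.11, −0.12 and 0.67, and the sexes of the wild type −0.08, 0.06 and 0.25.

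Alternatives were the median of ratios, library size alone and TMM without germline and yolk lists as scalings, other count filters, DESeq2 1.42.0, limma-voom, limma-trend on log2 TPM, the compared groups alone, unrounded counts, a replicate block, and each library left out in turn, which leaves 2 in its group. The code was tested on simulated data with effects in 200 genes per comparison, 50 at each size. At a log2 fold change of 1 it recovered 14, 8, 20, 10 and 2% in the order of the 5 comparisons above, and at 2 it recovered 70, 80, 84, 70 and 42%, with 4, 4, 3, 0 and 2 unchanged genes called.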

Results

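Transcript levels of hlh-30 (IV, 4014793 to 4034951, build WBcel235), which encodes the TFEB homolog HLH-30, were lower in both sexes of the hlh-30(tm1978) strain. Its level was 14.1 ± 1.2 CPM (counts scaled to a common library size, mean ± SD of 3 libraries) in wild-type hermaphrodites and 3.33 ± 0.32 in hlh-30 hermaphrodites. In males it was 38.9 ± 1.9 CPM in the wild type and 9.48 ± 0.89 in the mutant. The log2 fold change was −2.08 ± 0.16 (SE) in hermaphrodites and −2.04 ± 0.15 in males (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.9e-04 and 2.0e-04). The interaction of sex and genotype for hlh-30 was 0.04 ± 0.21 (adjusted p = 1). Levels of hlh-30 were 13.53, 13.26 and 15.45 CPM in the wild-type hermaphrodite libraries and 3.06, 3.68 and 3.26 in the mutant ones. They were 37.9, 37.8 and 41.1 CPM in wild-type males and 10.36, 9.53 and 8.57 in hlh-30 males. Counts per gene do not resolve the deleted part of the gene. In the wild type, hlh-30 was higher in males than in hermaphrodites by a log2 fold change of 1.47 ± 0.15 (adjusted p = 9.87e-06), and in the mutant strain by 1.51 (adjusted p = 1.76e-05).

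**Figure D1:**
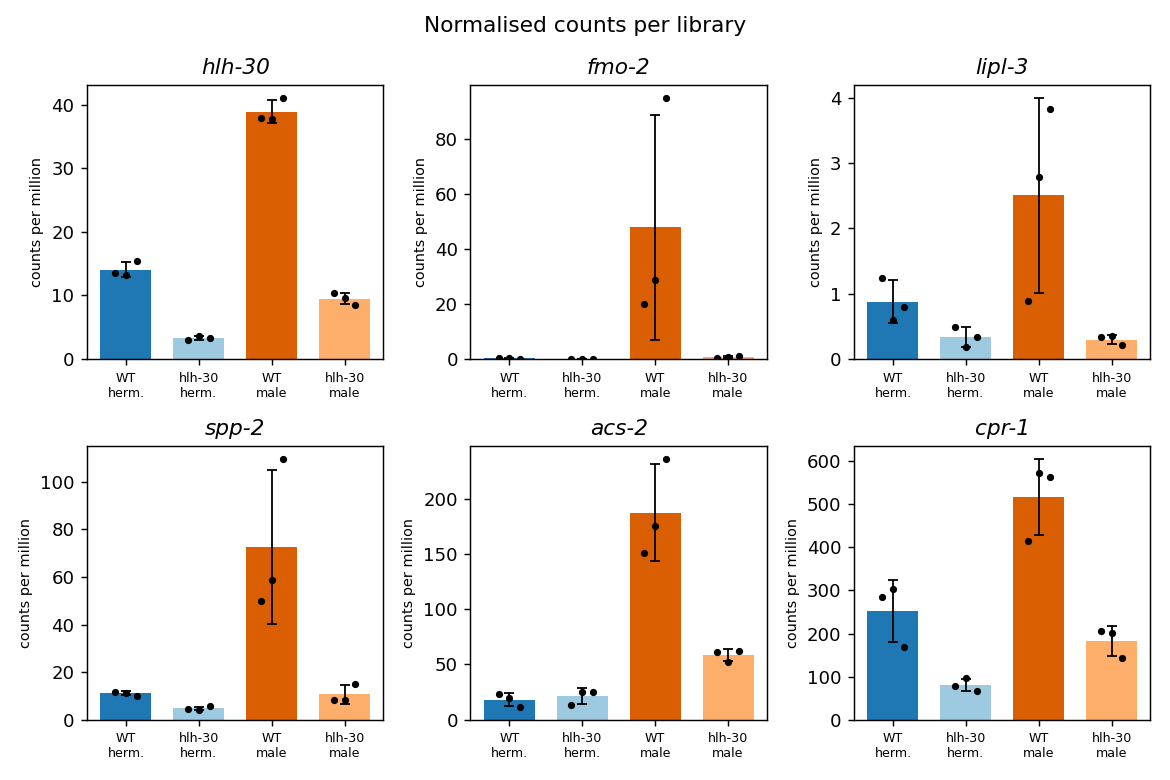
Levels of 6 genes in CPM (y axis) in the 4 groups of animals (x axis). Bars are means, error bars are SD and points are the 3 libraries of each group.

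Wild-type males differed from wild-type hermaphrodites in most of the genes tested, with sperm, neuron and immune effector genes higher in males and yolk, oocyte and ribosomal genes lower. Of 16645 genes, 6733 were higher in males and 5181 lower at an adjusted p under 0.05, 71.6% of the genes tested. With an absolute log2 fold change of at least 1, 5825 were higher and 3920 lower. The all-gene median log2 fold change was 0.27, and moved by −0.10 with the median of ratios and by 0.10 with library size alone. The ± values are SEs for log2 fold changes and SDs for CPM (3 libraries per group).

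Among genes with a mean count of at least 10 per library in both groups and no overlap between them, the largest rises in males were those of F59B2.12 (log2 fold change 12.98 ± 1.17, adjusted p = 4.85e-06), from 0.633 to 5096 CPM, B0207.5 (10.21 ± 0.93), C49C3.11 (10.11 ± 0.68), Y74C10AR.2 (8.66 ± 0.90) and try-11 (8.20 ± 0.98). The largest such falls were those of dhs-26, a short-chain dehydrogenase (−5.30 ± 0.61, adjusted p = 2.21e-05), Y57G11B.5 (−5.24 ± 0.86), K10C2.8, T12B5.15 (−5.04 ± 0.69) and D1086.7 (−5.03 ± 0.82). A further 220 genes past the test had 0 counts in every wild-type hermaphrodite library. Among them, clec-94 was at least 5518-fold and C16C8.9 at least 2362-fold higher in males, from a floor of 3 counts per library. Another 25 genes had 0 counts in all wild-type male libraries, with lsy-27 at least 83.6-fold and fbxb-7 at least 41.8-fold lower in males. Both lie in the stretch of chromosome V at 0 in wild-type males, and hlh-30 males had 35.33 and 21 mean counts, so that sex need not be the reason. F59B2.12 overlaps a neighbour by 131 nt of exon and lsy-27 by 59, so their values may hold reads of another gene if counting was unstranded.

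All 29 tested genes of the major sperm proteins, the cytoskeletal proteins of nematode sperm, rose in males (median log2 fold change 3.55), among them msp-55 (4.05 ± 0.40) and msp-53 (3.59 ± 0.35). In the spermatogenesis list 41 of 42 genes rose and 1 fell (median 3.73), with spe-6, a sperm kinase, at 3.45 ± 0.22 and spe-8 at 3.81 ± 0.25. Genes of the male tail and male neurons rose in 15 of 16 (median 6.98, and 5.02 with 2 members at their bound), with the polycystin gene pkd-2 going from 0.0689 to 46.8 ± 1.0 CPM (9.26 ± 0.39). All 3 lists passed the camera test (adjusted p = 1.3e-09, 7.2e-12 and 1.1e-05), but not with the correlation between genes estimated from the data (adjusted p = 0.415, 0.385 and 0.198 with an estimated correlation). Copies of the msp genes are near identical, so that their reads are shared among them.

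The 6 vitellogenins, yolk proteins made by the hermaphrodite intestine, all fell in males (median −3.62, camera adjusted p = 0.0340, and adjusted p = 0.554 with an estimated correlation). The changes ran from vit-1 (−4.03 ± 1.22, adjusted p = 0.0116) to vit-2 (−3.06 ± 1.05, adjusted p = 0.0219). Oocyte and eggshell genes fell in 27 of 28, with the eggshell gene cpg-3 at −4.07 ± 0.89 and egg-3 at −1.97 ± 0.42 (median −3.04, adjusted p = 7.8e-06, and adjusted p = 0.549 with an estimated correlation). Germline genes fell in 20 of 23, or 23 when adjusted over the list alone, with the synaptonemal complex gene syp-2 at −1.54 ± 0.16 (median −1.48, adjusted p = 1.3e-05, and adjusted p = 0.415 with an estimated correlation). Early embryo genes fell in 4 of 5, or 5 over the list alone, with pes-10 at −3.17 ± 0.70 (median −2.30, adjusted p = 0.0422, and adjusted p = 0.290 with an estimated correlation). Without wild-type male library 2 the calls of vit-2 to vit-6 were lost (adjusted p = 0.0511 to 0.0693), and without wild-type male library 3 that of the vitellogenin list (adjusted p = 0.0543). The early embryo call was lost without wild-type hermaphrodite library 2, wild-type male library 1 or 3, or hlh-30 male library 3 (adjusted p = 0.0511, 0.0580, 0.0510 and 0.0670).

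These hermaphrodite transcripts were not evenly spread over the male libraries. The median vitellogenin level was 17.3, 6.04 and 1.18% of the hermaphrodite level in wild-type male libraries 1, 2 and 3, and 23.73, 12.63 and 0.482% in the hlh-30 male libraries. For oocyte and eggshell genes the values were 21.5, 11.5 and 2.41% and 33.02, 19.2 and 2.29%.

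**Figure D2:**
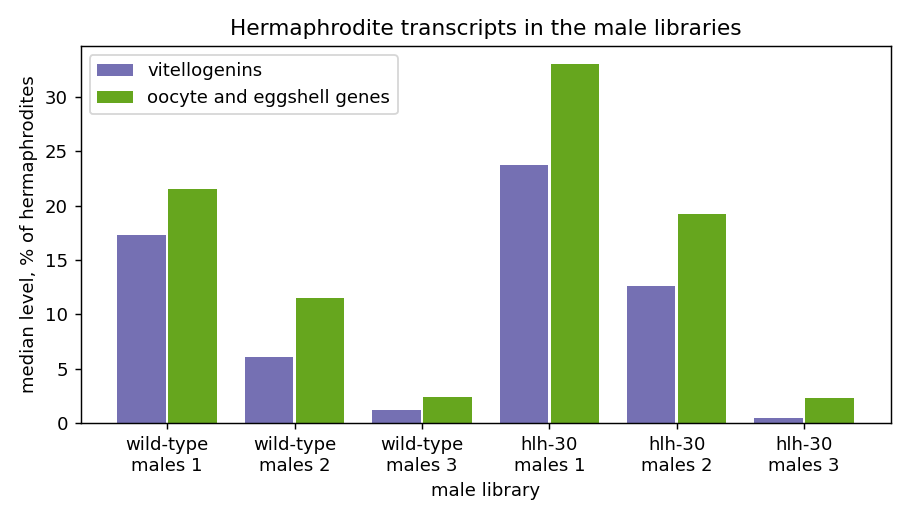
Median level of the 6 vitellogenins and the 28 oocyte and eggshell genes in each male library (x axis), as a percent of the mean of the hermaphrodite libraries of the same genotype (y axis). Each bar is 1 library, without error bars.

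Immune effector genes were mostly higher in wild-type males. C-type lectins, many of which are induced by pathogens, rose in 135 of 176 genes and fell in 14 (138 and 14 over the list alone), with clec-92 going from 0.0701 to 170 ± 78 CPM (11.12 ± 0.61) and clec-74 at 5.57 ± 0.31. Antimicrobial peptides and caenopores rose in 32 of 42 and fell in 0, with nlp-31 at 3.79 ± 0.35 and cnc-2 at 5.24 ± 0.48. Of the pathogen response genes of the p38 kinase PMK-1, 16 of 17 rose and 1 fell, with K08D8.5 at 4.03 ± 0.23. Their medians were 2.92 (2.58 with 17 lectins at their bound), 1.72 (1.6 with 3 members at their bound) and 2.50, with camera adjusted p = 3.6e-10, 1.6e-05 and 4.4e-05, and adjusted p = 0.290, 0.415 and 0.413 with an estimated correlation. Lysozymes rose in 8 of 12 and fell in 4, the list not passing (median 1.76, adjusted p = 0.3005): lys-3 was at 7.59 ± 0.64, lys-10 at 3.13 ± 0.95 and the invertebrate-type ilys-5 at −1.95 ± 0.27. Genes of the intracellular pathogen response, the pals family, rose in 12 of 22 and fell in 1, with pals-6 at 4.92 ± 0.52 (median 1.29, adjusted p = 0.0472, and adjusted p = 0.554 with an estimated correlation). That call was lost without wild-type hermaphrodite library 1 or 2 or wild-type male library 3 (adjusted p = 0.0518, 0.0779 and 0.137).

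Autophagy genes were mostly lower in wild-type males, whereas the cargo receptor gene sqst-1 was higher. Of 28 genes, 15 fell and 4 rose (median −0.71, camera adjusted p = 0.0166, and adjusted p = 0.415 with an estimated correlation). The 4 that rose were sqst-1 (1.89 ± 0.18, adjusted p = 5.99e-06), from 23.4 ± 2.7 to 86.6 ± 13 CPM, epg-5 (1.16 ± 0.14), atg-2 (1.07 ± 0.20) and the kinase gene unc-51 (1.08 ± 0.23). Among those that fell were epg-8 (−1.26 ± 0.13, adjusted p = 1.2e-05) and bec-1 (−0.81 ± 0.15), subunits of the VPS-34 complex, the ubiquitin-like lgg-3 (−1.51 ± 0.24) and the conjugation gene atg-16.1 (−1.25 ± 0.16). Of these 15, vps-34 was lost without wild-type hermaphrodite library 2 (adjusted p = 0.0564). The vps-15 call was lost without wild-type hermaphrodite libraries 1 and 2 or wild-type male libraries 2 and 3 (adjusted p = 0.0508 to 0.0883). The epg-2 call was lost without any wild-type library but hermaphrodite library 1 (adjusted p = 0.0596 to 0.177).

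Lysosomal lipases, enzymes of lipophagy, rose in 6 of 7 (median 2.49, camera adjusted p = 0.0307, and adjusted p = 0.290 with an estimated correlation), with lipl-5 going from 89.5 ± 1.8 to 958 CPM (3.42 ± 0.30), lipl-2 at 4.21 ± 0.46 and lipl-3 at 1.5 ± 0.51. The lipl-3 call was lost without wild-type hermaphrodite library 2 or 3 or wild-type male library 2 or 3 (adjusted p = 0.0756, 0.0598, 0.0545 and 0.104). V-ATPase subunits, the proton pump of the lysosome, fell in 12 of 21 and rose in 0 (9 over the list alone), with vha-7 at −1.97 ± 0.34 (median −0.37, adjusted p = 0.00202, and adjusted p = 0.290 with an estimated correlation). Other lysosome genes rose in 15 of 34 and fell in 4 (14 and 3 over the list alone), with the cathepsin B gene cpr-3 at 4.06 ± 0.28 and the cholesterol transporter gene ncr-2 at 3.65 ± 0.27 (median 0.38, adjusted p = 0.264). Of 16 reported HLH-30 targets, 7 rose and 4 fell (median 0.51, adjusted p = 0.726), among them the flavin monooxygenase gene fmo-2 from 0.257 ± 0.15 to 48.0 ± 41 CPM (7.5 ± 0.74, adjusted p = 8.22e-06) and vps-11 at −1.05 ± 0.25. The fall of vha-15, another of them, was lost without wild-type hermaphrodite library 3 or wild-type male library 1 or 2 (adjusted p = 0.0741, 0.0580 and 0.0828).

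Neuronal genes were higher in wild-type males and the protein synthesis machinery lower. Neuropeptides rose in 46 of 52 and fell in 0, with flp-14 at 2.62 ± 0.18 (median 2.41), and markers of neurons rose in 18 of 19, with the processing enzyme gene egl-21 at 2.35 ± 0.20 (median 1.83). Ribosomal proteins fell in 79 of 80 and rose in 1, rpl-42 (3.02 ± 0.35), with a median of −1.21. Proteasome subunits fell in 23 of 31, with pbs-3 at −1.12 ± 0.16 (median −0.73). Camera gave adjusted p = 1.0e-09, 8.0e-05, 8.0e-13 and 1.0e-05 for these 4 lists, and adjusted p = 0.290, 0.198, 0.415 and 0.475 with an estimated correlation. Detoxification genes rose in 97 of 170 and fell in 22 (97 and 21 over the list alone), with the cytochrome P450 gene cyp-35B1 at 6.71 ± 0.36 (median 0.96). DAF-16 targets rose in 11 of 12 and fell in 1, with the glyoxylate cycle gene icl-1 at 2.59 ± 0.23 (median 1.74). Adjusted p was 0.00155 and 0.00722, and adjusted p = 0.549 and 0.290 with an estimated correlation.

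Sex determination and dosage compensation genes fell in 11 of 21 and rose in 4 in wild-type males, with fog-3, needed for sperm fate, at 4.29 ± 0.32 and fem-3 at −2.32 ± 0.25 (median −0.56, camera adjusted p = 0.0326, and adjusted p = 0.616 with an estimated correlation). Without wild-type hermaphrodite library 2 or wild-type male library 3 that list did not pass (adjusted p = 0.0511 and 0.0542). Lipid metabolism genes rose in 7 of 36 and fell in 13 (7 and 12 over the list alone), with the acyl-CoA synthetase gene acs-2 at 3.35 ± 0.33 and the desaturase gene fat-7 at −2.29 ± 0.24 (median −0.18, adjusted p = 0.222). Collagens rose in 35 of 131 and fell in 36 (31 and 36 over the list alone), with a median of 0.78 and a mean of 0.68 but camera pointing down (adjusted p = 0.422). Heat shock genes rose in 9 of 19 and fell in 6 (median 0.38, adjusted p = 0.867), body wall muscle genes rose in 6 of 11 (0.52, 0.188) and pharynx genes in 3 of 10 (0.77, 0.713). Intestine genes rose in 3 of 10 and fell in 3, with a median of 0.21 and a mean of 0.10 but camera pointing down (adjusted p = 0.767). Of 12 genes of the mitochondrial genome 0 passed (median −0.80, adjusted p = 0.265), with ND6 at −1.44 (adjusted p = 0.189). The 2250 X-linked genes tested had a median of 0.28 and autosomal genes of 0.26, a difference of 0.02 (limma's camera with its preset correlation, p = 0.938). Among genes at 1 CPM or more in both wild-type groups the medians were 0.09 (1508 X-linked) and −0.20 (10563 autosomal), not tested.

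**Figure D3:**
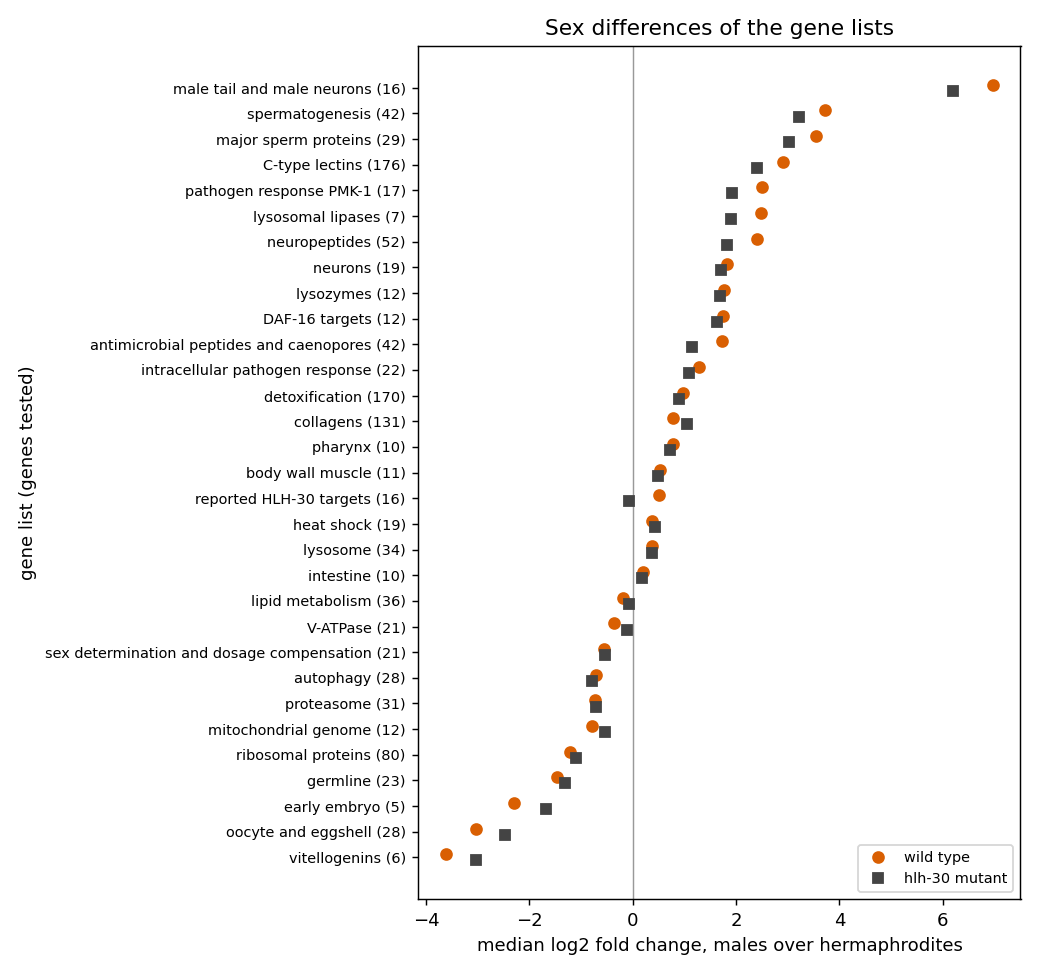
Median log2 fold change of males over hermaphrodites (x axis) for the genes tested in each of the 31 lists (y axis, number of genes in brackets), in the wild type and in the hlh-30 strain, without error bars. With library size alone as the scaling, the medians of V-ATPase, reported HLH-30 targets and lipid metabolism in the hlh-30 strain change sign.

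In the hlh-30 strain too, sperm, male neuron and immune effector genes were higher in males, and yolk, oocyte and ribosomal genes were lower. Of 16645 genes 6555 were higher and 4815 lower in hlh-30 males than in hlh-30 hermaphrodites (68.3%), and 5587 and 3382 with an absolute log2 fold change of at least 1. The all-gene median was 0.26, which moved by −0.14 with the median of ratios and by 0.15 with library size alone. With a mean count of at least 10 in both groups and no overlap, the largest rises were those of F59B2.12 (11.22 ± 1.1, adjusted p = 1.49e-05), F26D2.16 (10.93 ± 1.1), Y51A2D.8 (10.03 ± 0.70), B0207.5 (9.75 ± 0.91) and Y74C10AR.2 (8.32 ± 0.88). The largest such falls were those of dhs-26 (−5.76 ± 0.61), T22B7.7 (−5.40 ± 0.44), K10C2.8 (−4.23 ± 0.67), W07A12.8 (−4.12 ± 0.40) and T12B5.15 (−3.96 ± 0.65). At 0 counts in all hlh-30 hermaphrodite libraries were 186 genes past the test, with C16C8.19 at least 723.6-fold and Y49F6B.20 at least 684.7-fold higher in males. The reverse held for 1 gene, T08D2.6, with too few counts for a fold.

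Reproductive lists differed between the sexes of the hlh-30 strain. Major sperm proteins rose in 29 of 29, spermatogenesis genes in 41 of 42 with 1 fall, and male tail and male neuron genes in 15 of 16, with spe-6 at 2.83 ± 0.21 and pkd-2 at 8.88 ± 0.39. The medians were 3.02, 3.22 and 6.20 (5.61 with 1 member at its bound), and camera gave adjusted p = 1.7e-09, 1.3e-11 and 4.8e-06, and adjusted p = 0.427, 0.396 and 0.142 with an estimated correlation. All 6 vitellogenins fell, with vit-1 at −3.65 ± 1.19, and oocyte and eggshell genes fell in 22 of 28 (26 over the list alone) and germline genes in 20 of 23. Their medians were −3.04, −2.47 and −1.32 (adjusted p = 0.0309, 6.1e-06 and 5.4e-06, and adjusted p = 0.506, 0.506 and 0.427 with an estimated correlation). Early embryo genes fell in 5 of 5 (median −1.69, adjusted p = 0.0361, and adjusted p = 0.285 with an estimated correlation). With the replicate number as a block that list did not pass (adjusted p = 0.0547), nor without hlh-30 male library 1 or 2 (adjusted p = 0.0632 and 0.0526). The calls of vit-2 (−2.48 ± 1.03, adjusted p = 0.0498) and vit-6 were lost without any of 8 libraries, all but wild-type male libraries 1 and 3 and hlh-30 male libraries 1 and 3 (adjusted p = 0.0527 to 0.102). Those of vit-3, vit-4 and vit-5 were lost without hlh-30 hermaphrodite library 2 or hlh-30 male library 2, and of vit-4 and vit-5 also without hlh-30 hermaphrodite library 1 (adjusted p = 0.0529 to 0.0705).

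Immune effector lists were higher in hlh-30 males too. C-type lectins rose in 122 of 176 and fell in 11 (124 and 11 over the list alone), with clec-92 at 10.27 ± 0.59 and clec-62 at 2.95 ± 0.17 (median 2.40, and 2.22 with 15 members at their bound). Antimicrobial peptides and caenopores rose in 32 of 42 and fell in 0, with abf-1 at 7.07 ± 0.83 (median 1.14). PMK-1 pathogen response genes rose in 15 of 17, with K08D8.5 at 2.90 ± 0.22 (median 1.93). The pals genes rose in 11 of 22, with pals-6 at 4.32 ± 0.45 (median 1.1). Camera gave adjusted p = 1.6e-09, 9.7e-05, 9.7e-05 and 0.0361, and adjusted p = 0.285, 0.427, 0.427 and 0.506 with an estimated correlation. The call of the pals list was lost without hlh-30 hermaphrodite library 1 or hlh-30 male library 3 (adjusted p = 0.0534 and 0.0923). Lysozymes rose in 8 of 12 and fell in 2 (median 1.68, adjusted p = 0.119), with lys-3 at 6.60 ± 0.62 and lys-10 at 4.93 ± 1.1. DAF-16 targets rose in 9 of 12 and fell in 1, with the catalase gene ctl-1 at 1.82 ± 0.18. Detoxification genes rose in 96 of 170 and fell in 19 (96 and 18 over the list alone), with ugt-43 at 7.30 ± 0.43. Their medians were 1.62 and 0.90 (adjusted p = 0.00635 and 0.00176, and adjusted p = 0.285 and 0.506 with an estimated correlation).

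Autophagy genes fell in 16 of 28 and rose in 4 in hlh-30 males, with sqst-1 at 1.45 ± 0.18, epg-8 at −1.20 ± 0.13 and atg-13 at −1.33 ± 0.15 (median −0.80, adjusted p = 0.00176, and adjusted p = 0.356 with an estimated correlation). The fall of vps-15 was lost without wild-type hermaphrodite library 2, wild-type male library 2, hlh-30 hermaphrodite library 1 or 2 or hlh-30 male library 3 (adjusted p = 0.0503 to 0.1197). Lysosomal lipases rose in 6 of 7, with lipl-2 at 3.85 ± 0.46 and lipl-5 at 1.90 ± 0.28 (median 1.90, adjusted p = 0.0384, and adjusted p = 0.356 with an estimated correlation, or adjusted p = 0.0547 with the replicate number as a block). The rise of lipl-1 (1.52 ± 0.50) was lost without hlh-30 hermaphrodite library 1 or hlh-30 male library 3 (adjusted p = 0.0762 and 0.0546). Of the reported HLH-30 targets 7 of 16 rose and 5 fell, with fmo-2 at 4.59 ± 1.07. Their median of −0.07, which is above 0 with library size alone, and camera (adjusted p = 0.974) pointed down but their mean, 0.77, up. V-ATPase genes fell in 4 of 21 (2 over the list alone) and rose in 0, with a median of −0.11 that is above 0 with library size alone (adjusted p = 0.0546). Without wild-type hermaphrodite library 1 or 2 or hlh-30 male library 3 that list passed (adjusted p = 0.0472, 0.0480 and 0.0231). Lysosome genes rose in 14 of 34 and fell in 6, with cpr-3 at 3.46 ± 0.28 (median 0.38, adjusted p = 0.381).

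Neuropeptides rose in 45 of 52 and fell in 1 in hlh-30 males (46 and 1 over the list alone), with the insulin-like ins-31 at 10.90 ± 0.92, and neuron markers rose in 17 of 19, with unc-13 at 1.90 ± 0.19. Ribosomal proteins fell in 78 of 80 and rose in 1 (79 and 1 over the list alone), and proteasome subunits fell in 24 of 31, with pas-4 at −1.02 ± 0.16. The medians were 1.83, 1.70, −1.09 and −0.72 (adjusted p = 2.6e-08, 5.1e-05, 1.3e-13 and 8.4e-07, and adjusted p = 0.285, 0.169, 0.427 and 0.427 with an estimated correlation). Sex determination genes rose in 2 of 21 and fell in 9 (median −0.54, adjusted p = 0.0244, and adjusted p = 0.605 with an estimated correlation), a call lost without hlh-30 male library 3 (adjusted p = 0.0615). Lists that did not pass were collagens (39 of 131 higher and 22 lower, 37 and 21 over the list alone, median 1.05, adjusted p = 0.7905). So were heat shock (10 of 19 and 4, 10 and 5 over the list alone, 0.44, 0.7905) and lipid metabolism (6 of 36 and 8, −0.07, 0.267), whose median is above 0 with library size alone. Muscle genes rose in 4 of 11 (0 over the list alone, 0.49, 0.264, or 0.0415 without hlh-30 male library 3) and pharynx genes in 3 of 10 (1 over the list alone, 0.73, 0.585). Intestine genes rose in 1 of 10 and fell in 1 (0 over the list alone), with a median of 0.19 but camera pointing down (adjusted p = 0.921). The block by replicate number gave 7 lower heat shock genes, 5 higher pharynx genes, and 2 higher and 2 lower intestine genes. Genes of the mitochondrial genome passed in 0 of 12 (median −0.54, adjusted p = 0.114), but with the replicate number as a block 6 were lower and the list passed (adjusted p = 0.0209), as it did without hlh-30 hermaphrodite library 2 or hlh-30 male library 3 (adjusted p = 0.0403 and 0.00711). The 2250 X-linked genes exceeded autosomal genes by a median of 0.11 (limma's camera with its preset correlation, p = 0.354), with medians of 0.17 and −0.21 among those 1508 and 10563 genes.

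In hermaphrodites few genes changed with hlh-30. The lysosomal cathepsin B gene cpr-1 fell from 252 ± 73 to 80.6 ± 15 CPM (−1.65 ± 0.27, adjusted p = 0.0313) and the ferritin gene ftn-1 from 1.91 ± 0.95 to 0.093 ± 0.058 CPM (−4.30 ± 0.60, adjusted p = 0.0110). Histone genes of a cluster on chromosome II fell too, with his-12 going from 295 ± 32 to 13.8 ± 3.5 CPM (−4.42 ± 0.34, adjusted p = 1.93e-04) and his-15 from 1044 to 49.5 CPM (−4.40 ± 0.37). In all, 11 genes were higher and 32 lower in hlh-30 than in wild-type hermaphrodites (11 and 31 with an absolute log2 fold change of at least 1). Without hlh-30 hermaphrodite library 1, 2 or 3 the lower genes numbered 20, 21 and 19. The cpr-1 call was lost without wild-type hermaphrodite libraries 1 and 2, wild-type male library 2, any hlh-30 hermaphrodite library or hlh-30 male library 1 (adjusted p = 0.0515 to 0.188). The ftn-1 call was lost without any hlh-30 hermaphrodite library (adjusted p = 0.0510, 0.0824 and 0.0900).

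Of genes at a mean count of at least 10 in both groups, without overlap, the largest rises in hlh-30 hermaphrodites were those of F07B7.2 (copies at V, 8828165 to 8873535, each at 4.0 ± 0.42, adjusted p = 0.00124), C38D9.2 (3.97 ± 0.49), F15D4.5 (3.31 ± 0.43) and the scramblase gene scrm-4 (2.59 ± 0.25). The largest such falls were those of Y73B3A.1 near the left end of X (−4.98 ± 0.61, adjusted p = 0.00365), his-12, ZK131.14 (−4.41 ± 0.34) and his-15. Copies of these histone genes and of F07B7.1 and F07B7.2 are near identical and ZK131.14 overlaps a neighbour by 150 nt of exon, hmt-1 by 70 and bgal-2 by 50. Each value may hold reads of its copies or of the overlapping gene, as the strand setting is unknown. Among genes chosen after their values were seen, the heavy metal transporter gene hmt-1 went from 74.7 ± 7.3 to 6.95 ± 2.3 CPM (−3.43 ± 0.42, adjusted p = 0.00365) and bgal-2 from 25.4 ± 2.2 to 1.69 ± 0.36 CPM (−3.91 ± 0.32, adjusted p = 2.57e-04).

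Most lists held 0 genes past the test in this comparison (edgeR's quasi-likelihood test; 712 of all genes had an unadjusted p under 0.05, and limma-voom called 9 higher and 32 lower and DESeq2 35 and 70). The lysosome list held 1 lower gene, cpr-1 (1 higher and 2 lower over the list alone), and the DAF-16 targets 1, ftn-1. Over the list alone the lysosomal lipases held 2 higher and 1 lower gene and the reported HLH-30 targets 1 lower gene, with lipl-1 at −2.35 ± 0.50 (adjusted p = 0.15 over all genes). Autophagy genes passed in 0 of 28 (median −0.06, camera adjusted p = 0.411), with bec-1 at −0.15 and lgg-2 at −0.24 (adjusted p = 1 for each).

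Camera placed 8 lists past its threshold in hermaphrodites, of whose genes cpr-1 and ftn-1 alone were called. Collagens (median 0.65, adjusted p = 0.00207), body wall muscle (0.21, 0.0227), neuropeptides (0.13, 0.0302), spermatogenesis (0.10, 0.0468) and PMK-1 pathogen response (0.19, 0.0468) pointed up. DAF-16 targets (−0.20, 0.0120), lipid metabolism (−0.10, 0.0339) and lysosome (−0.12, 0.0468) pointed down. The smallest adjusted p = 0.687 with an estimated correlation, for DAF-16 targets and lipid metabolism, and adjusted p = 0.939 with an estimated correlation for the other 6. The number of lists was 0 without wild-type hermaphrodite library 2 (adjusted p = 0.0960 to 0.601, with the spermatogenesis median at −0.07), 4 without hlh-30 hermaphrodite library 2, and 5 without wild-type male library 3, hlh-30 male library 2 or hlh-30 male library 3. Beyond wild-type hermaphrodite library 2, the collagen call was lost without hlh-30 hermaphrodite library 2 or 3 (adjusted p = 0.0842 and 0.201). The muscle and neuropeptide calls were lost without hlh-30 hermaphrodite library 2 (0.104 and 0.0842). The DAF-16 call was lost without hlh-30 hermaphrodite library 1 or 3 (0.0606 and 0.0917). The lysosome call was lost without wild-type hermaphrodite library 1 or hlh-30 hermaphrodite library 1 or 3 (0.135, 0.0547 and 0.247), and with library size alone (0.0605). After subtraction of hermaphrodite RNA the spermatogenesis, lysosome, PMK-1 and lipid metabolism calls ended (0.0542 to 0.078). Those of lipid metabolism, spermatogenesis and PMK-1 were lost without wild-type male library 3 or hlh-30 male library 2 or 3 (0.0513 to 0.0963). Lipid metabolism was also lost without wild-type hermaphrodite library 1 or hlh-30 hermaphrodite library 2 (0.0577 and 0.152). Spermatogenesis was lost without hlh-30 hermaphrodite library 2 or 3 (0.0842 and 0.409). PMK-1 was lost without wild-type hermaphrodite library 3 or hlh-30 hermaphrodite library 3 (0.0525 and 0.517).

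The other lists did not pass in hermaphrodites. Their medians and camera adjusted p were 0.10 and 0.791 for vitellogenins, 0.04 and 0.744 for oocyte and eggshell, 0.24 and 0.684 for early embryo, −0.08 and 0.393 for germline, 0.07 and 0.292 for major sperm proteins and 0.27 and 0.292 for male tail and male neurons. They were −0.06 and 0.684 for lysosomal lipases, −0.04 and 0.474 for V-ATPase, −0.10 and 0.248 for reported HLH-30 targets, −0.07 and 0.266 for lysozymes, 0.18 and 0.744 for antimicrobial peptides and −0.06 and 0.393 for heat shock. For detoxification they were −0.03 and 0.6, for ribosomal proteins −0.03 and 0.530, for the proteasome −0.05 and 0.276, for the mitochondrial genome −0.17 and 0.684 (0.0389 without hlh-30 hermaphrodite library 3), for neurons 0.13 and 0.411, for the pharynx 0.36 and 0.276 and for the intestine −0.03 and 0.684. Some of these lists passed without 1 library. Major sperm proteins did so without wild-type hermaphrodite library 3 or hlh-30 hermaphrodite library 2 (0.00682 and 0.0186), lysozymes and reported HLH-30 targets without wild-type hermaphrodite library 3 (0.0477 and 0.0484), and the pharynx without wild-type hermaphrodite library 1 or hlh-30 hermaphrodite library 3 (0.029 and 0.0389). Germline, proteasome and ribosomal proteins passed without hlh-30 hermaphrodite library 1 (0.0401, 3.4e-04 and 2.7e-04) and detoxification without hlh-30 hermaphrodite library 3 (0.0148). Signs differed in 3 lists: sex determination had a median of −0.01, above 0 with the median of ratios, and a mean of 0.08 with camera up (0.744), C-type lectins a median of 0.03 with camera down (0.684) and pals genes a median of 0.09 and a mean of −0.07 with camera down (0.744). Medians of the 2250 X-linked and the autosomal genes differed by −0.01 (limma's camera with its preset correlation, p = 0.414).

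In hlh-30 males 30 genes were higher and 69 lower in the model of all 12 libraries. The noncoding RNA tts-1 fell from 802 ± 463 to 2.73 CPM (−8.20 ± 0.84, adjusted p = 0.00137). The target gene fmo-2 fell from 48.0 ± 41 to 0.747 ± 0.31 CPM (−6.0 ± 0.67, adjusted p = 0.00200) and the alcohol dehydrogenase gene adh-1 from 407 to 18.3 CPM (−4.48 ± 0.57, adjusted p = 0.00456), though adh-1 overlaps a neighbour by 70 nt of exon. The caenopore gene spp-2 fell from 72.7 ± 32 to 10.6 ± 4.0 CPM (−2.77 ± 0.34, adjusted p = 0.00366) and the C-type lectin gene clec-166 from 19.3 to 3.79 CPM (−2.35 ± 0.29, adjusted p = 0.00421). The cathepsin gene cpr-1 fell from 516 to 183 CPM (−1.50 ± 0.26, adjusted p = 0.0321). The lipase gene lipl-3 fell from 2.50 ± 1.5 to 0.299 ± 0.072 CPM (−3.04 ± 0.56, adjusted p = 0.0379) and acs-2 from 187 to 58.7 CPM (−1.67 ± 0.31, adjusted p = 0.0389).

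Other large falls were those of T22F3.11 (−4.65 ± 0.50, adjusted p = 0.00157) and fbxa-24 (−4.45 ± 0.63, adjusted p = 0.00853). The largest rises among genes seen in every group were those of F07B7.2 (3.29 ± 0.41, adjusted p = 0.00409), F07B7.1 (3.22) and F15D4.5 (2.79 ± 0.42, adjusted p = 0.0137), the first 2 with near-identical copies. A further 14 genes past the test had 0 counts in all wild-type male libraries, with scl-24 at least 180.1-fold and the pseudogene WBGene00007677 at least 29.1-fold higher in hlh-30 males. These 14 lay in a stretch of chromosome V, from 17339084 to 17552859, in which 22 neighbouring genes had 0 counts in wild-type males, against 2984 counts in wild-type hermaphrodites, 2371 in hlh-30 hermaphrodites and 3552 in hlh-30 males. At 0 in all hlh-30 males were 2 genes at the left end of X, WBGene00022222 (at least 10.2-fold lower) and T08D2.6 (at least 3.33-fold lower).

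**Figure D4:**
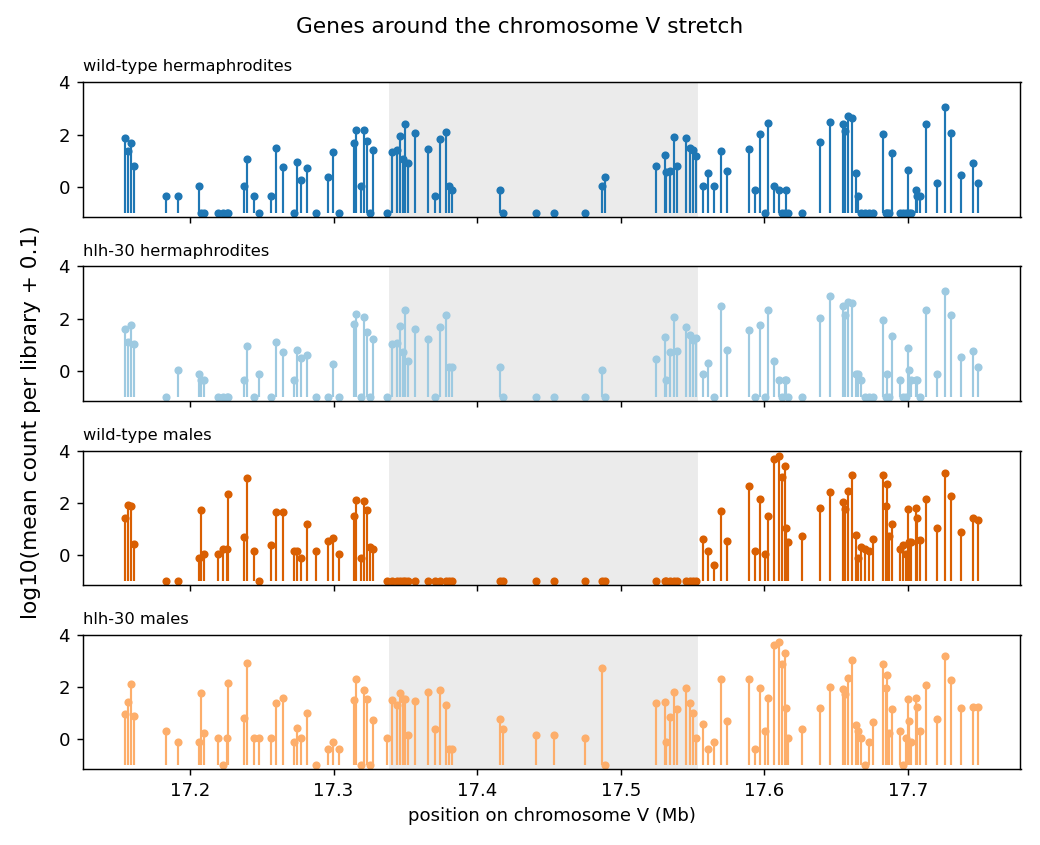
Mean count per library of each annotated gene with a mean count of at least 1 in any group (y axis, log10 of the count plus 0.1) against its position on chromosome V in Mb (x axis), in the 4 groups of animals. The grey band is the stretch of 22 genes with 0 counts in wild-type males, and no error bars are drawn.

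With an absolute log2 fold change of at least 1, 30 genes were higher and 63 lower in hlh-30 males. With the replicate number as a block, which these 2 groups share, the counts were 82 and 189. Without wild-type male library 2 or 3 or hlh-30 male library 1 or 2 they were 16 and 32, 16 and 30, 18 and 21, and 17 and 22, and with only the 6 male libraries in the model 0 and 6, where the 6 hermaphrodite libraries alone gave 11 and 41. With a block within each sex the counts in males were 548 and 529, and with hermaphrodite RNA subtracted 78 and 83, so that the majority of lower genes depends on the model. The lipl-3 call was lost without any library except wild-type male library 1 (adjusted p = 0.0544 to 0.178). The acs-2 call was lost without any except wild-type hermaphrodite library 3, wild-type male library 1 and hlh-30 hermaphrodite library 1 (adjusted p = 0.0571 to 0.189). The cpr-1 call was lost without wild-type male library 2 or 3, hlh-30 hermaphrodite library 2 or hlh-30 male library 1 or 2 (adjusted p = 0.05001 to 0.149). The F15D4.5 call was lost without wild-type male library 2 or 3 or hlh-30 male library 1 (0.0604, 0.0562 and 0.0638). The fbxa-24 call was lost without hlh-30 male library 1 (0.0638).

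Lists of immune effectors pointed down in hlh-30 males. C-type lectins fell in 4 of 176 and rose in 1 (12 and 1 over the list alone), falling in clec-166, clec-48 (−0.99 ± 0.17), clec-7 (−1.44) and clec-53 (−0.98) and rising in clec-72 (1.18 ± 0.22), of which clec-7, clec-53 and clec-72 were named after their values were seen. Antimicrobial peptides and caenopores fell in 1 of 42, spp-2 (5 over the list alone), with nlp-28 at −2.31 ± 0.47 (adjusted p = 0.0613, or 0.0159 with the replicate number as a block, and 0.0478 and 0.00743 without wild-type male library 1 or hlh-30 male library 3). PMK-1 pathogen response genes fell in 1 of 17, K08D8.5 (−1.29 ± 0.21, adjusted p = 0.0169, 2 genes over the list alone), with dod-24 at −1.26 ± 0.29 (adjusted p = 0.0977, or 0.0132 with the block). The lower genes of these lists numbered 10, 4 and 3 with the replicate number as a block. The medians were −0.37, −0.15 and −0.27 (camera adjusted p = 3.7e-06, 0.00151 and 0.0228, and adjusted p = 0.501, 0.719 and 0.731 with an estimated correlation). Without wild-type male library 3 or hlh-30 male library 1 or 2 the antimicrobial list was lost (adjusted p = 0.0595, 0.108 and 0.0662), as was the PMK-1 list (0.104, 0.216 and 0.0662), which was also lost after subtraction of hermaphrodite RNA (0.0512). The clec-48 call was lost without 6 libraries, wild-type hermaphrodite 2, wild-type males 1 and 2, hlh-30 hermaphrodite 2 and hlh-30 males 1 and 2 (0.0527 to 0.1504). The K08D8.5 call was lost without any male library except wild-type male 1 (0.0596 to 0.109).

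Lysosome, lipase and autophagy lists pointed down as well, while V-ATPase genes pointed up. The lysosome list held 1 fall, cpr-1 (3 over the list alone), with cpr-4 at −1.09 ± 0.22 (adjusted p = 0.0615, or 0.00845 with the replicate number as a block and 0.0383 without hlh-30 male library 3), a median of −0.23 and camera adjusted p = 0.00313, and adjusted p = 0.475 with an estimated correlation. Lysosomal lipases fell in 1 of 7, lipl-3 (1 higher and 4 lower over the list alone, median −0.77, adjusted p = 0.0390, and adjusted p = 0.480 with an estimated correlation). Reported HLH-30 targets fell in 2 of 16, fmo-2 and lipl-3 (median −0.39, adjusted p = 0.00178, and adjusted p = 0.475 with an estimated correlation). Autophagy genes passed in 0 of 28 (1547 of all genes had an unadjusted p under 0.05, and limma-voom called 37 higher and 99 lower and DESeq2 155 and 265), or 1 lower over the list alone. Their median was −0.11 (adjusted p = 0.0435, and adjusted p = 0.614 with an estimated correlation), with the Atg8 homologs lgg-2 at −0.71 ± 0.16 (adjusted p = 0.0944, or 0.0432 with the block) and lgg-1 at −0.89 ± 0.31 (0.341, or 0.0199 with the block). V-ATPase genes passed in 0 of 21, with vha-12 at 0.33 ± 0.15 (median 0.18, adjusted p = 5.0e-04, and adjusted p = 0.475 with an estimated correlation). With the replicate number as a block the lipases (adjusted p = 0.0572) and autophagy (0.0551) did not pass, and 3 lysosome genes, 3 reported targets and 2 autophagy genes were lower. The lipase call was also lost without wild-type male library 3 or hlh-30 male library 1 or 2 (0.107, 0.134 and 0.0969) and after subtraction of hermaphrodite RNA (0.0512). The autophagy call was lost without wild-type hermaphrodite library 1 or 2, wild-type male library 1 or 3 or hlh-30 male library 2 or 3 (0.0502, 0.0599, 0.0890, 0.111, 0.0969 and 0.162) and with library size alone (0.0999).

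Collagens and oocyte genes pointed up and sperm lists down in hlh-30 males, each with 0 genes past edgeR's test (1547 of all genes had an unadjusted p under 0.05, and limma-voom called 37 higher and 99 lower and DESeq2 155 and 265). A block by replicate number gave 1 higher collagen. With a block within each sex 24 collagens were higher and 1 lower, 8 oocyte genes higher, and 8 major sperm protein and 3 spermatogenesis genes lower. Collagens had a median of 1.19 (camera adjusted p = 4.0e-17, and adjusted p = 0.501 with an estimated correlation), with col-166 at 1.39 ± 0.44 (adjusted p = 0.278). Their geometric mean level was 29.3, 24.2 and 9.81 CPM in wild-type male libraries 1, 2 and 3 and 55.4, 39.5 and 19.7 in the hlh-30 ones. Spermatogenesis genes had a median of −0.45 (adjusted p = 5.6e-07, and adjusted p = 0.614 with an estimated correlation), with the sperm chromatin gene spch-3 at −0.78 ± 0.24 (adjusted p = 0.263), and major sperm proteins of −0.33 (adjusted p = 0.00313, and adjusted p = 0.907 with an estimated correlation). Oocyte and eggshell genes had a median of 0.66 (adjusted p = 0.0390, and adjusted p = 0.907 with an estimated correlation). The hlh-30 male libraries 1 and 2 also held the larger shares of vitellogenin transcripts, 23.73 and 12.63%, against 17.3 and 6.04% in the wild type. Without wild-type male library 3 the major sperm protein median was 0.14 (0.904) and the oocyte median 0.18 (0.382), and without hlh-30 male library 1 the oocyte median was −0.11 (0.712). The oocyte call was also lost without hlh-30 hermaphrodite library 1 or hlh-30 male library 2 (0.0527 and 0.565) and with library size alone (0.0866). The major sperm protein call was lost without hlh-30 male library 1 or 2 (0.270 and 0.147).

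Neuropeptides fell in 1 of 52, the insulin-like ins-20 (−3.71 ± 0.60, adjusted p = 0.0352), with a median of −0.31 (camera adjusted p = 3.7e-06, and adjusted p = 0.480 with an estimated correlation). DAF-16 targets fell in 1 of 12, ftn-1 (−2.79 ± 0.45, adjusted p = 0.0169, 3 genes over the list alone), with icl-1 at −1.04 ± 0.22 (0.0676, or 0.0345 with the replicate number as a block) and a list median of −0.22 (adjusted p = 0.0435, and adjusted p = 0.501 with an estimated correlation). With the block 3 DAF-16 targets were lower and that list did not pass (adjusted p = 0.0761), nor without wild-type hermaphrodite library 2, wild-type male library 2 or 3 or hlh-30 male library 1 or 2 (0.0558, 0.0984, 0.0635, 0.0967 and 0.0969), nor after subtraction of hermaphrodite RNA (0.0946). Detoxification genes fell in 2 of 170, cyp-37B1 (−3.28 ± 0.54) and cyp-13A5 (−2.0 ± 0.26), or 3 over the list alone (median −0.08, adjusted p = 0.149, 6 lower genes with the block, or 8.6e-04 without hlh-30 male library 3). The ins-20 call was lost without any library except wild-type hermaphrodites 2 and 3 (0.0531 to 0.179). The ftn-1 call was lost without wild-type male library 3 or any hlh-30 male library (0.0605 to 0.109). The cyp-37B1 call was lost without wild-type male library 2 or 3 or hlh-30 male library 1 or 2 (0.0748 to 0.129). That of cyp-13A5 was lost without hlh-30 male library 2 (0.0657).

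Lists that did not pass in males were vitellogenins (median 0.70, camera adjusted p = 0.552), germline (0.02, 0.766), male tail and male neurons (−0.37, 0.0819), sex determination (0.08, 0.394), pals genes (−0.07, 0.766), heat shock (0.08, 0.642) and ribosomal proteins (0.09, 0.172), whose median without hlh-30 male library 1 was −0.16 (0.0315). So were proteasome (−0.08, 0.471), neurons (−0.05, above 0 with library size alone, 0.745), body wall muscle (0.06, 0.324) and pharynx (0.45, 0.172). Without hlh-30 male library 3 the vitellogenins (0.00235), germline (0.00366), male tail and male neurons (0.0280), sex determination (0.00835), ribosomal proteins (1.0e-10), body wall muscle (0.0119) and pharynx (0.0452) passed. The pharynx also passed without wild-type male library 2 (0.0272). Signs differed in 5 lists: early embryo (median −0.14, mean 0.42, camera up, 0.418), lysozymes (median −0.06, camera up, 0.847), lipid metabolism (1 fall, acs-2, median 0.01, below 0 with the median of ratios and with TMM without germline genes, mean −0.04, camera down, 0.847), mitochondrial genome (median 0.10, camera down, 0.394, 1 lower gene with the replicate number as a block, or 7.7e-04 without hlh-30 male library 3) and intestine (median −0.004, above 0 with library size alone, camera up, 0.771). X-linked genes exceeded autosomal genes by 0.12 (medians 0.08 and −0.04, camera p = 9.6e-04, and p = 0.0910 with an estimated correlation).

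Genes past the test in both sexes changed in the same direction. These were 5 higher genes, F15D4.5 and the copies of F07B7.1 and F07B7.2 (0.0198 expected for independent lists, Fisher's exact p = 6.1e-12), and 11 lower ones (0.133 expected, p = 3.2e-19), with 0 in opposite directions. These tests count copies and neighbours as independent. A refit without runs of neighbours gave overlaps of 1 and 2 but lost other calls too. Besides hlh-30 the 11 held cpr-1, ftn-1, the patched-related ptr-22, tts-1 and 6 genes near the left end of X, chkr-1 among them. The overlap of lower genes was 7 without wild-type hermaphrodite library 1 or 2, 5 without wild-type male library 2 or hlh-30 hermaphrodite library 1 or 3, 6 without hlh-30 hermaphrodite library 2 and 4 without hlh-30 male library 1 or 2. That of higher genes was 9 without hlh-30 male library 3, and with the replicate number as a block the overlaps were 10 and 19. Of the 99 genes called in males, 78 had the same sign in hermaphrodites (16 past the test), and of the 43 called in hermaphrodites 37 had the same sign in males.

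**Figure D5:**
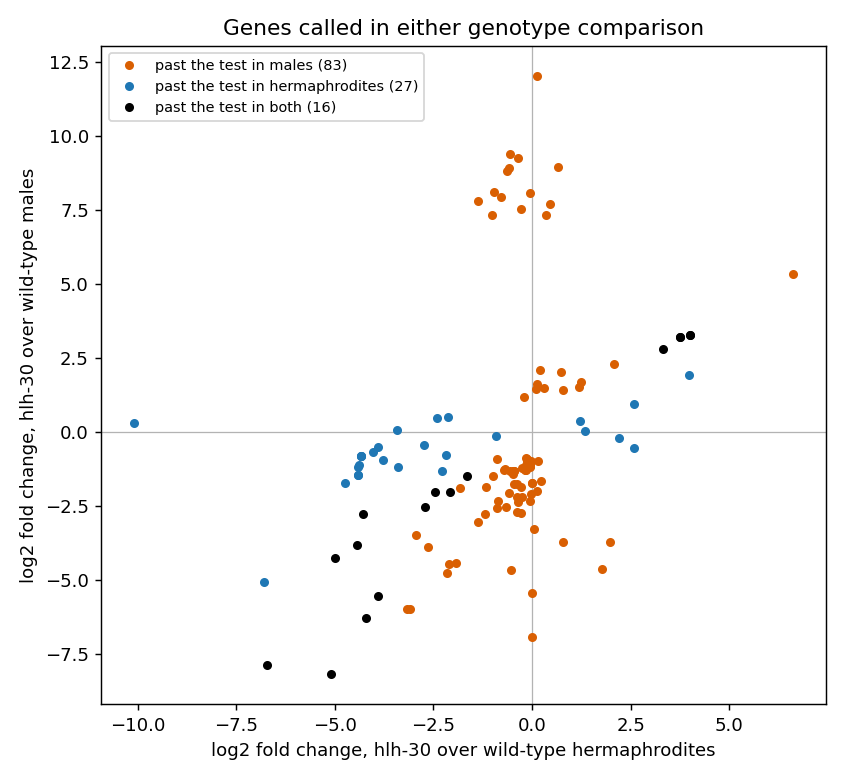
Log2 fold change of hlh-30 over wild-type males (y axis) against that of hlh-30 over wild-type hermaphrodites (x axis) for each gene past the test in either comparison, without error bars. Fitted values of genes with 0 counts in a group, such as the group of genes above 7 on the y axis, depend on the prior count and are no bounds.

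Male-biased genes made up most of the genes that were lower in hlh-30 males. Of the 69, 62 were higher in wild-type males than in wild-type hermaphrodites (27.9 expected for independent lists). The 5 with the largest falls were tts-1, dct-8 (−6.95 ± 0.53, adjusted p = 0.00232), fmo-2, dct-7 (−5.98 ± 0.64, adjusted p = 0.00421) and F56D6.8 (−5.46 ± 0.82, adjusted p = 0.0466), whose call was lost without any 1 of the 12 libraries (adjusted p = 0.0531 to 0.203). Of these, dct-8, dct-7 and F56D6.8 lie within 1 Mb of hlh-30, where variants linked to the deletion are not told apart from an effect of HLH-30. At an unadjusted p under 0.05 the overlap was 650 (340.5 expected for independent lists). In 20 draws of simulated data with no effect and the same shared libraries it was 66.2 on average (9.1 expected). Shared wild-type male libraries thus raise such an overlap, but the draws held no sex effect, so how much of the 650 or the 62 they account for was not tested. The count of 62 was 41 without wild-type hermaphrodite library 1, 27 and 23 without wild-type male libraries 2 and 3, and 19 without hlh-30 male library 1 or 2, and 161 with the replicate number as a block.

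A test of the interaction asked which of these effects differed between the sexes. The genes lower in hlh-30 males named above did not pass it: fmo-2 was at −2.91 ± 2.22 (adjusted p = 1), tts-1 at −3.09 ± 1.23 (0.975), adh-1 at −2.38 ± 0.72 (0.6), spp-2 at −1.58 ± 0.45 (0.544), clec-166 at −1.49 ± 0.41 (0.475), lipl-3 at −1.68 ± 0.80 (1), acs-2 at −1.90 ± 0.43 (0.256) and T22F3.11 at −6.42 ± 1.09 (0.0574). In the interaction 24 genes were higher and 4 lower, all of them also with an absolute log2 fold change of at least 1, against 24 and 10 with the replicate number as a block and 87 and 71 with a block within each sex. The 4 lower genes, whose level fell in hlh-30 males relative to the change in hermaphrodites, were F46C5.1 (−4.52 ± 0.49, adjusted p = 0.00390), C17F4.7 (−3.12 ± 0.52, adjusted p = 0.0493), the D-amino acid oxidase gene daao-1 (−2.45 ± 0.38, adjusted p = 0.0314) and C30F12.3 (−2.06 ± 0.29, adjusted p = 0.0175). In hlh-30 and wild-type males daao-1 was at 1.06 and 7.06 CPM and C30F12.3 at 4.72 and 20.1 CPM. In hermaphrodites they were at 0.903 and 1.098 CPM and at 1.85 and 1.89 CPM.

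Among genes with a mean count of at least 10 in all 4 groups, the largest positive interactions were those of the his-14 copies (3.53 ± 0.55, adjusted p = 0.0341), hmt-1 (3.48 ± 0.56, adjusted p = 0.0413) and bgal-2 (3.39 ± 0.42, adjusted p = 0.01), which were lower in hlh-30 hermaphrodites. Of the 24, 11 lay in the chromosome V stretch and 8 in the histone cluster of chromosome II, from 13817993 to 13827709, including his-12 at 2.96 ± 0.42. Leaving out 1 library gave 12 higher and 2 lower genes, 13 and 1, and 14 and 4 (wild-type hermaphrodites 1, 2 and 3), 10 and 1 and 11 and 1 (wild-type males 2 and 3), 10 and 1 and 13 and 2 (hlh-30 hermaphrodites 1 and 2), and 13 and 2 and 19 and 2 (hlh-30 males 1 and 2). The calls of hmt-1, C17F4.7 and daao-1 were each lost without 11 of the 12 libraries, hlh-30 male library 3, wild-type hermaphrodite library 3 and hlh-30 hermaphrodite library 3 being the exceptions (adjusted p = 0.0512 to 0.222). The his-14 calls were lost without any library except wild-type male 1, hlh-30 hermaphrodite 3 and hlh-30 male 2 (adjusted p = 0.0566 to 0.188). The C30F12.3 call was lost without any wild-type hermaphrodite library, wild-type male library 2 or 3 or hlh-30 hermaphrodite library 1 (adjusted p = 0.0522 to 0.0837).

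No list held a gene past the interaction test (775 of all genes had an unadjusted p under 0.05, and DESeq2 called 63 higher and 54 lower), but camera placed 8 lists past its threshold. With the replicate number as a block 1 gene each of C-type lectins, PMK-1 and detoxification was lower. A block within each sex gave 4 lower PMK-1 genes, 3 C-type lectins, 2 antimicrobial peptides and 1 gene each of lipases, reported targets and lysosome, 1 higher collagen, and 2 higher and 2 lower detoxification genes. Spermatogenesis (median −0.58, adjusted p = 9.4e-09), neuropeptides (−0.47, 6.5e-08), major sperm proteins (−0.53, 1.8e-04), PMK-1 pathogen response (−0.69, 2.2e-04, 3 lower over the list alone), antimicrobial peptides (−0.41, 7.9e-04) and C-type lectins (−0.36, 0.00524, 1 lower over the list alone) pointed down. Collagens (0.30, 4.2e-05) and V-ATPase (0.23, 1.8e-04) pointed up. Members with small p were sysm-1 (−2.35 ± 0.61, adjusted p = 0.379) and dod-24 (−1.68 ± 0.40, 0.294) of the PMK-1 list, clec-3 (−1.99 ± 0.36, 0.0867) and ins-4 (−2.40 ± 0.55, 0.256). The smallest adjusted p = 0.721 with an estimated correlation, for neuropeptides and V-ATPase, and adjusted p = 0.728 with an estimated correlation for the other 6. The number of lists was 4 without wild-type male library 3 or hlh-30 male library 1 and 15 without hlh-30 male library 3. Without wild-type male library 3 the calls of major sperm proteins (0.435), C-type lectins (0.269), antimicrobial peptides (0.121) and collagens (0.269) were lost, and without hlh-30 male library 1 the same 4 (0.0922, 0.123, 0.0922 and 0.0922). Major sperm proteins and antimicrobial peptides were also lost without hlh-30 male library 2 (0.0501 for each). C-type lectins were lost without hlh-30 hermaphrodite library 3 (0.0535) and after subtraction of hermaphrodite RNA (0.0564) and collagens without hlh-30 hermaphrodite library 1 (0.229).

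Among the lists that did not pass the interaction test were lysosomal lipases (median −0.37, camera adjusted p = 0.259, 1 lower over the list alone), with lipl-5 at −1.52 (adjusted p = 0.364), reported HLH-30 targets (−0.33, 0.224, 1 lower over the list alone), lysosome (−0.09, 0.224) and autophagy (−0.10, 0.235). Oocyte and eggshell genes had a median of 0.61 (0.169), germline of 0.10 (0.416), vitellogenins of 0.58 (0.709), early embryo of 0.44 (0.555), male tail and male neurons of −0.31 (0.169) and ribosomal proteins of 0.12 (0.169). Lysozymes were at 0.09 (0.253), DAF-16 targets at 0.22 (0.566), heat shock at 0.08 (0.297), detoxification at −0.08 (0.555), neurons at −0.16 (0.309), body wall muscle at −0.13 (0.555), intestine at 0.20 (0.566) and lipid metabolism at 0.02, below 0 with the median of ratios (0.253). Without hlh-30 male library 3 the oocyte (3.9e-09), germline (7.3e-04), vitellogenin (0.00486), ribosomal (1.5e-10), sex determination (0.0476) and detoxification (0.0134) lists passed. Oocyte genes also passed with the replicate number as a block (0.0145) and without wild-type male library 1 or 2 or hlh-30 hermaphrodite library 1 (9.1e-04, 0.0454 and 0.0270). Ribosomal proteins also passed without wild-type hermaphrodite library 1, wild-type male library 2 or hlh-30 hermaphrodite library 1 (0.0285, 0.0454 and 5.3e-05), and autophagy without wild-type hermaphrodite library 2 (0.0257). Signs differed in sex determination (median 0.05, mean −0.01, camera up, 0.632), proteasome (median −0.05, above 0 with library size alone, camera up, 0.940), mitochondrial genome (median 0.18, camera down, 0.566, or 0.0482 and 0.00175 without wild-type hermaphrodite library 3 or hlh-30 male library 3) and pharynx (median 0.14, mean −0.04, camera up, 0.788), and pals genes were at −0.18 (0.940). X-linked genes exceeded autosomal genes by 0.13 (camera p = 0.00126, and p = 0.101 with an estimated correlation), which was 0.05 (p = 0.0571) without hlh-30 hermaphrodite library 1.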

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

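Each result here passed the test of the interaction of sex and genotype, and the explanations, other splits of the libraries excepted, were weighed with tests chosen after the results were seen. In the interaction 24 genes were higher and 4 lower, or 87 and 71 with a block within each sex. The 3 copies of his-14 were at 3.525 each, hmt-1 at 3.48, bgal-2 at 3.39, F46C5.1 at −4.52, C17F4.7 at −3.12, daao-1 at −2.45 and C30F12.3 at −2.06. Among lists, the median was −0.529 for major sperm proteins, −0.581 for spermatogenesis, −0.355 for C-type lectins, −0.415 for antimicrobial peptides, −0.686 for the PMK-1 pathogen response and −0.470 for neuropeptides, and 0.226 for V-ATPase and 0.299 for collagens. X-linked genes exceeded autosomal genes by 0.127. With an estimated correlation 0 of these 8 lists passed (adjusted p = 0.721 to 0.728), and neither did the X-linked genes (p = 0.101).

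Of the 30 genes higher in hlh-30 males, 18 lay in runs of at least 3 neighbours, 4 of them near-identical F07B7 copies, where chance placement of the called genes gave at most 6 in 10000 permutations (mean 0.081, p = 1e-04, the smallest possible), which argues against chance. Of the 69 lower genes 10 lay in runs, where chance reached 12 (mean 1.005, permutation p = 0.001). A stretch of chromosome V missing from or unmappable in the wild-type male stock has the values it needs, from few counts: the 61 genes of its span that were neither called nor chosen for 0 counts there had 0 counts in wild-type males, against 22, 16 and 49 in the other groups. Variants linked to the hlh-30 deletion cannot be told apart from a biological effect of HLH-30, since 8 called genes, dct-8, dct-7 and F56D6.8 among them, lay within 1 Mb of hlh-30 in males (2.01 expected, Fisher's exact p = 9.2e-04) and no further cross is at hand; in hermaphrodites edgeR called 0 (0.862 expected), but 2 of the 8 had no count there and 5 of the other 6 had the same direction, 2 at an unadjusted p under 0.05. Differences between strains could also account for the histone run on chromosome II, with 8 genes, and the left end of X, with 11 falls in hermaphrodites.

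Hermaphrodite transcripts were present in the male libraries numbered 1 and 2. Carry-over from wild-type hermaphrodites is argued against by the chromosome V stretch, chosen for 0 counts in wild-type males. Their libraries 1 and 2 held 0 of 248 expected. Hermaphrodites among the picked males have the values they need, as the oocyte share was 1.243 to 1.905 times the vitellogenin share in the 4 libraries, if those animals lacked the stretch too. Expression of these genes by males cannot be told apart, since no single animals were measured; in the libraries numbered 3 the vitellogenin share was at most 1.178% and the oocyte share 2.41 and 2.29%.

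Spermatogenesis genes were lower and collagens higher in hlh-30 males. More hermaphrodite RNA in the hlh-30 male libraries is argued against as the whole cause, since after its subtraction the spermatogenesis median was −0.384, where it had been −0.447, and that of collagens 1.351. In pairs of equal number the differences were −0.372, −0.411 and −0.561 for spermatogenesis and 1.056, 0.896 and 1.207 for collagens. A developmental stage difference between male samples cannot be told apart, as stages are not given. With an estimated correlation neither list passed (camera adjusted p = 0.614 and 0.501). A biological difference by genotype stays open and was not tested.

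Other splits of the same libraries were tested for each comparison. For sex in the wild type, sex in hlh-30 and genotype in hermaphrodites, 1 of 10 splits, the real one, called as many genes (11914, 11370 and 43, highest other 0), and 10 splits are too few for a share under 0.05. For genotype in males 2 of 10 splits called at least the 99 genes of the real one, the highest other calling 123, while of the 4 splits that part all 3 pairs of equal number the highest other called 0. The split with 123 parts 1 of the 3 pairs and sets wild-type male library 1 and hlh-30 male libraries 1 and 2 apart, which points to structure of the samples that follows the share of hermaphrodite transcripts. For the interaction 4 of 100 splits called at least 28 genes, with 2090 at the highest, which points to structure of the samples; that split divides the males in the same way, but 9 of the 11 splits doing so called 0, and the other 2 splits, with 107 each, divide the males by genotype.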

How the results depend on the processing

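Alternatives were chosen before the data were examined except those marked as added, which were chosen after results were seen. The cause of changed results was not tested. Of 12987 gene results over all alternatives 12439 gave the same call, 409 were weaker and 139 stronger, and of 2790 list results 2528 were the same, 191 weaker, 66 stronger and 5 reversed. Depth limits genes near the floor of 3 counts per library.

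DESeq2 called 35 higher and 70 lower genes for genotype in hermaphrodites, 155 and 265 in males and 63 and 54 in the interaction, with all of the 43, 99 and 28 calls among them. With limma-trend on log2(TPM + 1) the counts were 61 and 122 in males, 31 lower in the interaction and 3002 lower for sex in hlh-30, and on log2(TPM + 0.1) 12 lower and 2868 lower. With only the groups compared and no block, 0 and 6 genes were called in males.

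With the replicate number as a block over all 12 libraries, 17 genes were higher in hermaphrodites, 82 higher and 189 lower in males and 10 lower in the interaction, the overlaps were 10 and 19, and male-biased genes lower in hlh-30 males numbered 161. It changed no other total of called genes by over 1.5 times. With a block within each sex (added) the counts were 54 and 87, 548 and 529, and 87 and 71, with overlaps of 23 and 43 and 419 male-biased genes, and with males alone and a block (added) 1317 and 1743. With both male libraries numbered 3 left out (added) 17 and 54 genes were called in hermaphrodites, the overlaps were 9 and 22 and 13 lists passed in the interaction. With hermaphrodite RNA subtracted at the vitellogenin share (added) 78 genes were higher in males and 39 and 9 called in the interaction, and 4 lists passed in hermaphrodites. With runs of neighbouring genes left out (added) the counts were 4 and 9 in hermaphrodites, 6 and 42 in males and 4 and 2 in the interaction, with overlaps of 1 and 2 and 41 male-biased genes. Leaving out ribosomal RNA genes (added) moved no count that far. With an estimated correlation 0 lists passed in each comparison, where 21, 20, 8, 14 and 8 had passed.

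With each library left out in turn, genes higher and lower ran from 6085 to 6951 and 4508 to 5709 for sex in the wild type, 5594 to 6542 and 3996 to 5157 for sex in hlh-30, 8 to 16 and 19 to 40 for genotype in hermaphrodites, 16 to 45 and 21 to 69 in males and 10 to 24 and 1 to 4 in the interaction. The overlaps ran from 4 to 9 and 4 to 11, and male-biased genes lower in hlh-30 males from 19 to 62. Lists ran from 17 to 21, 19 to 21, 0 to 10, 7 to 22 and 4 to 15 in the order above. The difference of X and autosomes ran from 0.003 to 0.035, 0.078 to 0.145, −0.065 to 0.052, 0.077 to 0.149 and 0.053 to 0.187.

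In 5 list results that passed with all 12 libraries or with 1 left out, camera's direction turned without that library. The spermatogenesis median in hermaphrodites was −0.069 without wild-type hermaphrodite library 2. In males the oocyte median was 0.176, still above 0, without wild-type male library 3 and −0.114 without hlh-30 male library 1, major sperm proteins were 0.138 without wild-type male library 3, and ribosomal proteins −0.158 without hlh-30 male library 1. With each library left out in turn these lists reached 0.249, 1.397, −0.784 and 0.352 at the other end, in the order spermatogenesis, oocyte, major sperm proteins and ribosomal proteins.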

Other observations

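On chromosome V, 1610 of 3387 genes were higher in wild-type males and 799 lower (median 0.69), and on IV 1289 of 2884 were higher and 852 lower (0.45). On I and III the balance was reversed, with 937 of 2670 higher and 1049 lower (−0.16) and 846 of 2489 higher and 949 lower (−0.15).

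The male libraries numbered 3 stood apart on the second principal component (5.4% of the variance), at 53.2 and 50.9 where other males were at −17.4 to −47.6. In them collagens were lowest (9.81 and 19.7 CPM) and spermatogenesis genes highest per genotype (112.8 and 77.1 CPM). Genes of the mitochondrial genome were highest in the libraries numbered 3 of all 4 groups, at 338.4, 174.5, 294.2 and 266.9 CPM.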
